A study of Homo sapiens with 6 samples.

How the data were processed

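The series holds 6 RNA-seq libraries, 3 labelled as 293T cells that overexpress STAT6 and 3 labelled as Mock control cells. 293T is a human embryonic kidney cell line that carries the SV40 large T antigen. STAT6 is a transcription factor activated by interleukin 4 and interleukin 13. Per the labels' protocols, RNA was isolated with an RNAiso reagent and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. The submitters' processing notes name FastQC, STAR, Salmon and edgeR, without versions, and the human build GRCh37. How the reads were assigned to genes, the strand setting and any filter are not given in the sources used here.

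Each deposited file gives 1 whole-number count per gene symbol and no normalized value. All 6 files list the same 38986 gene symbols. Only 17 symbols were identical to a human gene symbol in the same case, 16671 were equal to one only after they were put in capitals, and 16851 had forms used for mouse genes alone. The symbols are therefore mouse symbols, and the files and the labels differ in organism. The groups were kept as the labels give them. No mouse sequence or annotation was used here, so no coordinates are given.

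Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 12938 genes holding 99.9% of all counts. TMM factors lay between 0.968 and 1.03. The test was the 2-sided quasi-likelihood test (glmQLFit with robust = TRUE, glmQLFTest) with group as the only term, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Adjusted p-values below are from this test unless another is named. A fold change is the ratio of the libraries labelled STAT6 over those labelled Mock. CPM values are counts scaled to the TMM-adjusted library total, given as mean ± SD with n = 3 per group. Where a group held 0 counts of a gene, the fold is a lower bound set against a floor of 3 counts over the group, and where it held 1 to 3 counts the ratio has an exact conditional 95% interval. Intervals and floors cover counting error only.

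Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 against all other tested genes, again with an estimated correlation, and with fry, which tests the list alone. Adjustment was over the 41 lists fixed before the data were examined. These lists were written with human symbols: of 1012 entries 957 matched a mouse symbol of the same letters, 34 matched through a table of exceptions and 21 had no match. The matching was chosen after the data were seen to be mouse. A list of pigment cell genes and a list of extracellular matrix genes were added after the data were examined, and their p-values were adjusted over all 43 lists. Shares of counts were compared with an exact permutation test, 2-sided, over the 20 assignments of the libraries, which cannot give a p under 0.1.

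The genes named were chosen by a rule set before the data were examined. It takes the STAT and JAK genes and the 12 genes with the largest rise and the 12 with the largest fall that were past the threshold, had a mean of at least 2 CPM and did not overlap between groups. From each list it takes up to 4 members with the smallest adjusted p. It adds all mtDNA-encoded protein genes, Mfn1, Mfn2, Opa1, Dnm1l and Fis1, and the 5 genes with the smallest adjusted p in each direction. Symbols made of Gm and a number, LOC and a number, a clone name ending in Rik or a sequence accession were passed over among the largest changes, and this reading of genes without a name was fixed after the data were seen. A gene named outside the rule is marked as such, and some genes that the rule takes are not reported here.

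Alternatives planned before the data were examined were DESeq2 size factors, library totals alone and upper-quartile scaling in the same fit, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, Stat6 or the mtDNA genes left out of the totals, each library left out in turn, and an adjusted p of 0.01. Alternatives added after the data were seen left Gm26917 out of the totals, thinned all libraries to the smallest total, or tested for a change beyond 1.5-fold with glmTreat.

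The fit was tested on simulated counts drawn for 12958 genes with the libraries' own means, depths and dispersions, 50 genes being changed at each of 4 fold sizes. In this simulation edgeR recovered 60% of the genes changed 1.2-fold and 86% of those changed 1.5-fold. It recovered 96% of those changed 2-fold and 100% of those changed 4-fold. It called 20 of 12758 unchanged genes. Far fewer genes were changed in the simulation than were called in the data (72.6%), so these rates need not hold there.

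For a scan of neighbouring genes, chosen after the data were seen, 10670 of the 12938 tested genes (82.5%) were placed by name in the order of human genes in the assembly GRCh38.p14. The median log2 fold change was taken in each window of 20 consecutive genes and set against 1000 shuffles of the gene positions. On shuffled changes with 4 added blocks of 30 genes, the scan recovered 4 blocks shifted by 1.2 on the log2 scale. It recovered 3 shifted by 0.8, with 0 windows outside the blocks at either size. Only upward shifts were added, and fewer shuffles were used, so lower blocks and smaller shifts were not covered. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.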

Results

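RNA was sequenced from 6 libraries in 2 groups of 3, labelled as mCherry-positive 293T cells with wild-type STAT6 and with Mock. The comparison was made to ask how STAT6 acts on mitochondrial gene expression, in a series whose title concerns mitochondrial fusion and MFN2, a fusion protein of the outer mitochondrial membrane. The libraries labelled STAT6 held 23648304, 19894773 and 21096955 counts, and those labelled Mock held 22368757, 22748691 and 29802693. Between 17287 and 19367 genes had at least 1 count in a library. The labels number the libraries but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Within a group, the median chi-square of 2 libraries' counts was 1.46 to 2.48 times that of counting noise, so no library was a copy of another.

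Stat6 itself was lower, not higher, in the libraries labelled STAT6. It stood at 33.6 ± 1.53 CPM there (SD, n = 3) and at 94.4 ± 1.49 CPM in the libraries labelled Mock, a log2 fold change of -1.49 (SE 0.04, adjusted p = 7.47e-26, edgeR). Scaled to the library total alone, it was 34.4, 32.8 and 31.0 CPM against 98.0, 97.4 and 95.2 CPM. The files hold mouse gene symbols and 0 rows for human STAT6, whereas the labels name a human line. They also hold abundant transcripts of pigment cells: Tyr and Tyrp1, Dct, Pmel and Mlana, the last 4 chosen after their values were seen, together took 13920 to 15610 CPM in each library. The direction of every comparison below therefore follows the labels alone, and "higher" means higher in the libraries labelled STAT6, in which Stat6 was lower.

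**Figure D1:**
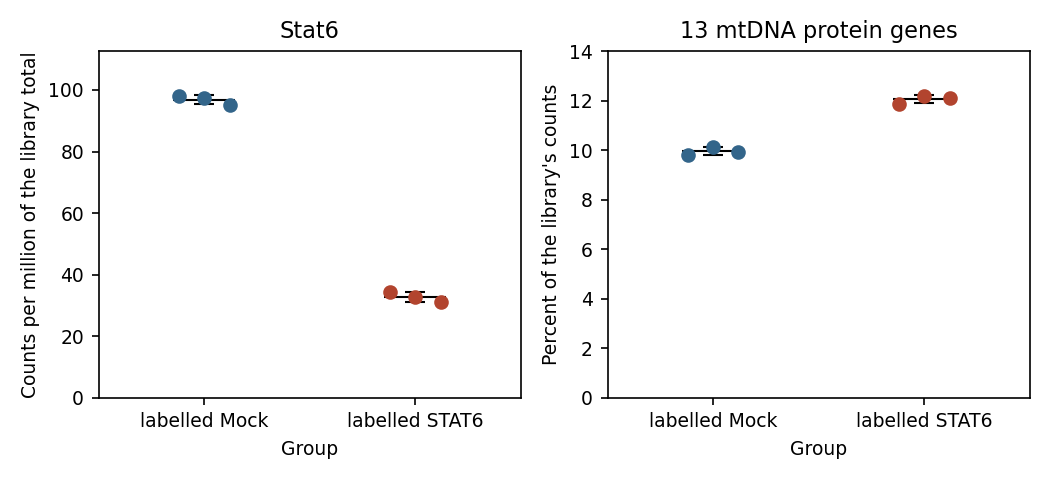
Stat6 in CPM of the library total (left) and the percent of each library's counts on the 13 mtDNA-encoded protein genes (right). Points are libraries, bars are the mean and SD of 3, and both axes start at 0. Stat6 lies between 31.0 and 34.4 in the libraries labelled STAT6 and between 95.2 and 98.0 in those labelled Mock, while the mtDNA share lies between 11.9% and 12.2% against 9.82% to 10.1%.

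The groups differed in most of the transcriptome. Of 12938 genes tested, 9399 (72.6%) passed the threshold, 4638 higher and 4761 lower in the libraries labelled STAT6. At least 2-fold changes were fewer, 1369 higher and 642 lower, or 15.5% of genes. The first principal component, which separated the groups, held 88.9% of the variance. Replicates were tight, with a biological coefficient of variation of 2.35% in the libraries labelled STAT6 and 3.74% in those labelled Mock, and 74.6% of genes had no overlap between groups where chance gives 10%. Much of the count rests on small changes that this spread resolves: a test for a change beyond 1.5-fold, added after the data were seen, called 2779 genes.

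Chemokine and matrix genes led the rise. Ccl2, which encodes a monocyte chemokine, had 28589 counts over the libraries labelled STAT6 and 3 over those labelled Mock, a ratio of 11630 (95% counting interval 3978 to 56380). Ccl7, a related chemokine, had 575 counts against 0 and was at least 234-fold higher. Cxcl1, a neutrophil chemokine, rose by 9.05 on the log2 scale (SE 0.13, adjusted p = 2.46e-35). Other large log2 fold changes were 7.64 for the collagen gene Col6a1, 7.12 for Igfbp7, 7.03 for Slfn2, 6.63 for Htra3, 6.57 for Adgra1, 6.51 for Lims2 and 6.42 for the cytokine gene Lif. Genes with the smallest adjusted p on this side, besides Ccl2, were Mcam (log2 fold change 4.39), Sparc (2.70), the cyclin gene Ccnd1 (2.59) and Akap12 (3.86). Mcam, an adhesion molecule of melanoma and endothelium, went from 39.9 ± 1.94 to 834 ± 7.70 CPM.

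On the other side, several genes were close to undetected in the libraries labelled STAT6. Capn6 had 1 count there against 3793, a ratio of 3109 (95% counting interval 557.7 to 122800). Osmr, the oncostatin M receptor, had 0 counts against 450 and was at least 123-fold lower, and Ldaf1, a lipid droplet gene, had 0 against 470 and was at least 128-fold lower. Other large falls, as log2 fold changes, were in Iqgap2 (-8.60), Foxr2 (-7.95), the actin regulator Enah (-7.88), the phosphatase gene Ptprd (-7.86) and the cadherin gene Cdh13 (-7.26). Arhgap32 had 3 counts against 1486, a ratio of 406, while Aff2 had 1 against 387, Ppp1r36dn 1 against 320 and Gca 2 against 360. The smallest adjusted p on this side belonged to Abca12 (log2 fold change -5.58), Epha3 (-4.73), Enah, Tyr (-3.38) and the desaturase gene Scd2 (-2.14). Tyr, the rate-limiting enzyme of melanin synthesis, went from 303 ± 5.29 CPM in the libraries labelled Mock to 29.1 ± 0.757. Genes with at least 2 CPM in each library of one group and at most 3 counts over the other numbered 8 for the libraries labelled STAT6 and 17 for those labelled Mock.

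Transcripts of the mitochondrial genome took a larger share of the libraries labelled STAT6. The 13 protein genes held 12.1% ± 0.157 of their counts (SD, n = 3) against 9.96% ± 0.155, a difference of 2.09 percentage points (exact permutation test, 2-sided, p = 0.1, the smallest that 20 assignments allow). Of these genes 12 rose and 1 fell. The rise was largest for ND4 (log2 fold change 0.72), ND6 (0.69), ND4L (0.67), COX2 (0.62), CYTB (0.60) and ND2 (0.45), and smaller for ND3 (0.32), ATP6 (0.23), ND1 (0.18), COX3 (0.18), ND5 (0.16) and COX1 (0.14). ATP8 was lower by a log2 fold change of -0.07 (adjusted p = 0.0292); this call was lost with DESeq2 (adjusted p = 0.0715) and without STAT6 replicate 1 (0.101), STAT6 replicate 3 (0.104) or Mock replicate 2 (0.138). ATP8 overlaps ATP6 and ND4L overlaps ND4, so the split of their reads is uncertain. As a list the 13 genes were higher with the preset correlation of 0.01 (camera, adjusted p = 0.0215). With the estimated correlation of 0.64 this call was lost (camera, adjusted p = 0.672). The mitochondrial rRNAs held 0.325% ± 0.0252 against 0.415% ± 0.0342 of counts (exact permutation test, p = 0.1), in libraries made from polyadenylated RNA. Of a pair of noncoding RNAs chosen after their values were seen, Malat1 took 0.046% ± 0.00589 of counts against 0.016% ± 0.00215, a ratio of 2.88 with no overlap (exact permutation test, p = 0.1), and Gm26917 took 1.41% ± 0.314 against 1.02% ± 0.232 (the same test, p = 0.3); whether RNA quality differed between the groups was not measured.

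Nuclear genes of oxidative phosphorylation did not move as one. Of 80 tested, 30 were higher, 32 lower and 18 not past the threshold, with a median log2 fold change of -0.00 and a mean of 0.06 (camera, adjusted p = 0.792). The smallest adjusted p belonged to Atp5d (1.41), Uqcr11 (1.22), Ndufs7 (1.21) and Uqcrq (0.58), subunits of complexes V, III, I and III. Of these, Uqcr11 and Ndufs7 lie in 1 block of neighbouring genes, described below, in which 48 of 54 genes were called higher. In complex I 16 were higher and 14 lower of 37 (adjusted p = 0.755), among them Ndufs8 (-0.79), Ndufb1 (0.76) and Ndufv3 (0.50). Complex II had 0 higher and 3 lower of 4 (adjusted p = 0.386), namely Sdhb (-0.38), Sdhd (-0.31) and Sdha (-0.24). In complex III 3 were higher and 5 lower of 9 (adjusted p = 0.755), with Cyc1 at -0.62, and its median of -0.11 and mean of 0.09 differed in sign. Complex IV had 6 higher and 1 lower of 12 (adjusted p = 0.691), led by Cox8a (0.33) and Cox7a2l (0.28). In complex V 5 were higher and 9 lower of 18 (adjusted p = 0.893), with Atp5pb at -0.46 and a median of -0.07 against a mean of 0.02. With fry, which tests a list without the other genes, complexes I (adjusted p = 0.0266), III (0.0211) and IV (0.0119) passed as higher and complex II (0.00521) as lower, while complex V (0.588) and the whole list (0.0757) did not pass. Adjusted over the list alone, each of these counts and those of the mtDNA genes was the same.

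Genes of mitochondrial fusion and fission split in both directions. Of 23 tested, 8 were higher, 9 lower and 6 not past the threshold, and the counts adjusted over the list alone were the same. Mfn2 was higher (log2 fold change 0.25, SE 0.04, adjusted p = 2.5e-07), at 100.3 ± 1.27 against 84.2 ± 1.39 CPM, whereas its partner in outer membrane fusion Mfn1 was lower (-0.39) and so was Opa1, the inner membrane fusion GTPase (-0.27). Among fission genes Fis1 (0.39) and Inf2 (0.94) were higher and Spire1 was lower (-0.49). Dnm1l, the fission GTPase, was higher by 0.12 (adjusted p = 0.00258), but with library totals alone the value was 0.04 (adjusted p = 0.259). Stoml2 was lower (-0.96) and Slc25a46 higher (0.44). The list as a whole did not pass with camera (adjusted p = 0.755) and passed as lower with fry (0.0191), its median (0.07) and mean (-0.06) differing in sign.

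Most lists of genes that build and maintain mitochondria had more lower than higher members in the libraries labelled STAT6. Mitochondrial ribosomal proteins had 9 higher and 57 lower of 80 (camera, adjusted p = 0.00365; adjusted p = 0.664 with an estimated correlation), for example Mrps30 (-0.83) and Mrpl42 (-0.61), against Mrpl44 (0.66). Mitochondrial chaperones and proteases had 1 higher and 11 lower of 14 (adjusted p = 0.035; adjusted p = 0.379 with an estimated correlation), including the chaperonin Hspd1 (-0.64) and Pitrm1 (-0.77). For mtDNA transcription, replication and RNA processing 5 were higher and 21 lower of 33, or 22 lower when adjusted over the list alone (adjusted p = 0.106; 0.0157 with no filter on low counts and 0.0285 with limma-voom), Lrpprc at -0.59 and Fastk at -0.99 against Tfam, which packages mtDNA, at 0.58. Protein import had 6 higher and 20 lower of 32, or 7 higher when adjusted over the list alone (adjusted p = 0.186; 0.0447 with no filter and 0.0455 with limma-voom), with Timm50 at -0.60 and Timm22 at 0.60. Biogenesis regulators had 2 higher and 10 lower of 16 (adjusted p = 0.15; 0.0447 with no filter), with Ppargc1a at -0.85 and Sirt1 at 0.86. Mitophagy genes had 10 higher and 4 lower of 18 (adjusted p = 0.12; 0.0263 with no filter), among them Optn (0.84) and Nbr1 (0.67). With fry all of these lists passed, at adjusted p from 3.72e-05 to 0.00417. Of the lists fixed beforehand, only complex V, nuclear oxidative phosphorylation and fatty acid oxidation did not pass with fry. A pass with fry therefore sets no list apart. The other counts of this paragraph were the same adjusted over the list alone.

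Sterol and fatty acid synthesis genes fell together in the libraries labelled STAT6. Of 25 cholesterol synthesis genes 24 were lower and 1 was higher, with a median log2 fold change of -1.41 (camera, adjusted p = 1.97e-36; adjusted p = 0.0179 with an estimated correlation). Cyp51, a sterol demethylase, went from 446.5 ± 6.60 to 68.1 ± 2.99 CPM (log2 fold change -2.71, SE 0.04, adjusted p = 1.47e-36), and Insig1 (-2.04), Fdps (-1.85) and Hmgcs1 (-1.64) fell as well. Of 14 fatty acid synthesis genes 12 were lower and 2 higher, with a median of -1.06 (adjusted p = 7.66e-14; adjusted p = 0.0179 with an estimated correlation). They included Fasn, the fatty acid synthase (-1.67), Elovl6 (-1.68), Fads2 (-1.51) and Srebf1, the transcription factor of this pathway (-1.60). Fatty acid oxidation genes were divided, 8 higher and 9 lower of 21 (adjusted p = 0.755), with the carnitine palmitoyltransferase gene Cpt1a at 0.87 and Echs1 at -0.90, a median of -0.01 and a mean of 0.07. Adjusted over the list alone, each count was the same.

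Inflammatory and antiviral genes rose. Of 16 genes of NF-kB and inflammatory cytokines 14 were higher and 1 was lower, with a median log2 fold change of 2.27 (camera, adjusted p = 6.45e-15; adjusted p = 0.0179 with an estimated correlation). Besides Ccl2, Cxcl1 and Lif they included Tnfaip3, an inhibitor of NF-kB signalling (5.15, SE 0.15, adjusted p = 1.23e-26). Interferon-stimulated genes had 28 higher and 3 lower of 33, with a median of 1.25 (adjusted p = 8.06e-11; adjusted p = 0.113 with an estimated correlation), among them Cxcl10 (2.60), Samd9l (1.90), Ifi27 (1.38) and Lgals3bp (1.25). All 10 tested genes of MHC class I and antigen presentation were higher, 7 of them at least 2-fold (adjusted p = 1.22e-05; adjusted p = 0.182 with an estimated correlation). B2m, the light chain of class I molecules, went from 297 ± 9.62 to 828 ± 27.6 CPM, and H2-K1 (1.63), Tapbp (1.53) and H2-D1 (1.40) rose too, reads of the closely related H2 genes being hard to assign. The counts were the same adjusted over the list alone.

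**Figure D2:**
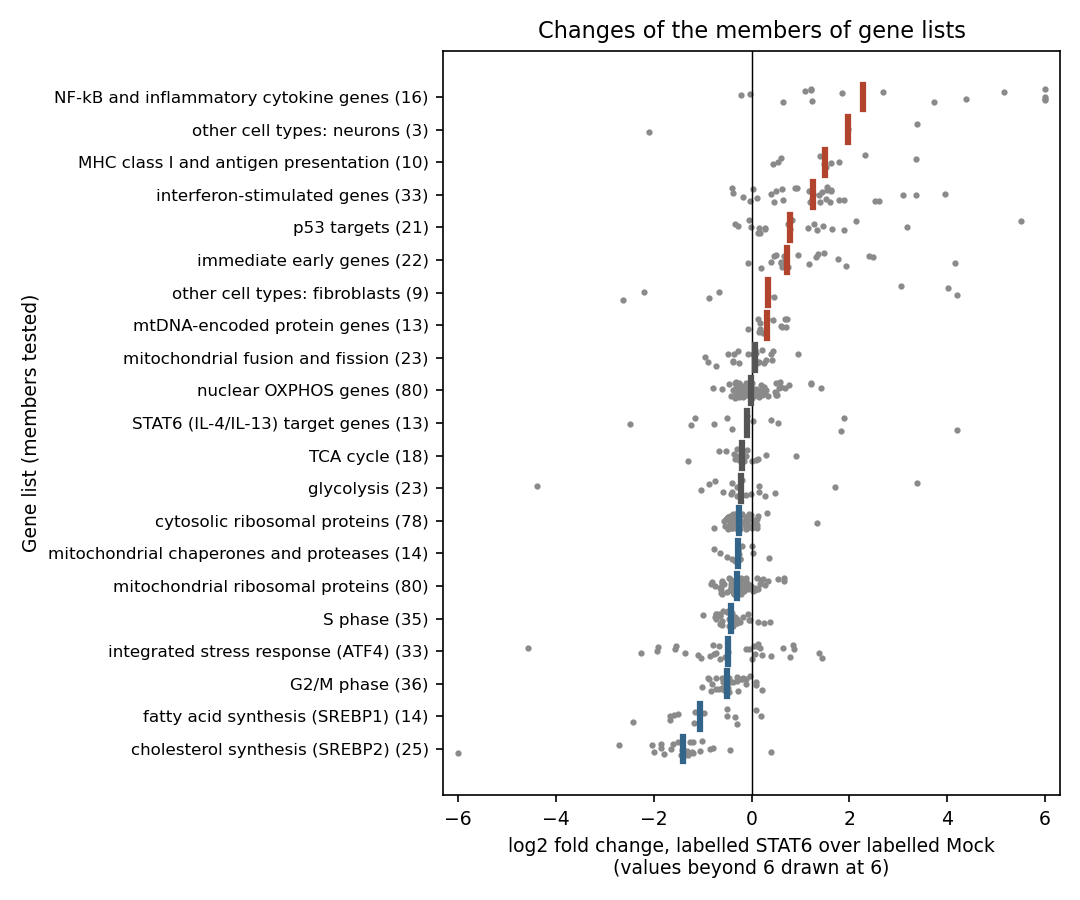
Log2 fold change of each tested member (grey points) of 21 gene lists, with the list's median as a bar, red or blue where camera with a preset correlation called the list higher or lower and grey where it did not. The horizontal axis is the log2 ratio of the libraries labelled STAT6 over those labelled Mock, and 5 members beyond 6 are drawn at 6. Medians run from -1.41 for cholesterol synthesis to 2.27 for NF-kB and inflammatory cytokine genes.

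Targets of p53 rose and most listed genes of the S and G2/M phases fell, while the cyclin gene Ccnd1, named above, rose (2.59). Of 21 p53 targets 16 were higher and 1 lower, with a median log2 fold change of 0.79 (camera, adjusted p = 1.26e-08; adjusted p = 0.0277 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 138 ± 3.78 to 604 ± 1.11 CPM (2.13, SE 0.03, adjusted p = 3.5e-35), and Btg2 (3.19), Trp53inp1 (1.34) and Mdm2 (1.28) rose. Genes of G2/M had 3 higher and 32 lower of 36, with a median of -0.51 (adjusted p = 7.03e-08; adjusted p = 0.127 with an estimated correlation), such as Birc5 (-1.02), Plk1 (-0.87), Ccnb1 (-0.83) and Ccna2 (-0.72). S phase genes had 3 higher and 29 lower of 35, with a median of -0.42 (adjusted p = 1.22e-05; adjusted p = 0.194 with an estimated correlation), such as Mcm7 (-0.66), Tyms (-0.65) and Mcm2 (-0.59). Immediate early genes had 19 higher and 0 lower of 22 (adjusted p = 1.25e-07; adjusted p = 0.0532 with an estimated correlation), among them Ccn2 (4.16), Ccn1 (2.39), Junb (1.93) and Jun (1.36). In the BCL2 family and caspases 10 were higher and 3 lower of 19 (adjusted p = 0.257; 3.4e-05 with fry), with the survival genes Bcl2l1 at 1.94 and Bcl2 at 0.77. Adjusted over the list alone, none of these counts changed.

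Cytosolic ribosomal protein genes shifted slightly but broadly, 8 higher and 64 lower of 78 with a median log2 fold change of -0.26 (camera, adjusted p = 1.22e-05; adjusted p = 0.664 with an estimated correlation). Rpl23a (-0.56) and Rpl8 (-0.53) were lower, and Rps15 (1.34) stood apart. These genes have many processed pseudogenes, so read assignment is uncertain. Among genes of the integrated stress response under ATF4, 8 were higher and 18 lower of 33 (adjusted p = 0.00275; adjusted p = 0.113 with an estimated correlation), the serine and asparagine synthesis genes Phgdh (-1.55), Asns (-1.10) and Psat1 (-0.86) being lower and Aldh1l2 (1.38) higher. The unfolded protein response had 7 higher and 15 lower of 24 (adjusted p = 0.106; 0.014 with no filter on low counts and 0.0455 with limma-voom), with the sensor gene Ern1 at 2.26 and its target Xbp1 at -1.64. Heat shock genes had 3 higher and 9 lower of 15 (adjusted p = 0.513), Cryab (1.26) and Hspb1 (2.10) against Hsp90ab1 (-0.52). The NRF2 antioxidant list had 6 higher and 13 lower of 20 (adjusted p = 0.106; 0.0157 with no filter), with Slc7a11 at -1.36 and Hmox1 at 0.79. In glycolysis 6 were higher and 16 lower of 23 (adjusted p = 0.397; 0.0371 with limma-voom), the hexokinase gene Hk1 at 1.71 and Ldha at -0.59. The TCA cycle had 4 higher and 12 lower of 18 (adjusted p = 0.0862), and the list passed with library totals alone (0.0466), no filter on low counts (0.0103) and limma-voom (0.0361) and without Mock replicate 2 (0.039), with Idh2 at -1.29 and Ogdh at 0.92. Hypoxia genes had 8 higher and 5 lower of 18 (adjusted p = 0.979), with P4ha1 at 1.06 and Vegfa at -2.45. With fry all lists of this paragraph passed, at adjusted p from 1.91e-07 to 0.0164, as did nearly all lists tested. Each count was the same adjusted over the list alone.

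Most other STAT and JAK genes were higher where Stat6 was lower. Of 10 tested 8 were higher, 1 was lower and 1 was not past the threshold (camera, adjusted p = 0.0852; with Stat6 left out of the table the adjusted p was 0.00353, with no filter on low counts 0.0274, with limma-voom 0.0177 and with fry 5.43e-06). Among them Stat3 (0.93), Stat5a (0.80), Stat5b (0.54), Jak1 (0.37), Stat2 (0.35) and Jak2 (0.34) were higher, as was Jak3 (2.33) at 3.10 ± 0.444 against 0.597 ± 0.294 CPM. Tyk2 had a log2 fold change of -0.01 (adjusted p = 0.862). Genes known as targets of STAT6 after interleukin 4 or 13 went both ways: 4 were higher, 6 lower and 3 not past the threshold of 13 (adjusted p = 0.815), with a median of -0.09 and a mean of 0.17. With fry the list passed as higher (adjusted p = 0.00916), and over its alternatives the adjusted p ran from 0.00916 to 0.915. Postn (4.21) and Tgm2 (1.89) were higher, Epas1 (-2.49) and Maoa (-0.77) lower. Both counts were the same adjusted over the list alone.

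Markers of other cell types were few among the tested genes and moved unevenly. Of 9 fibroblast markers 4 were higher and 4 lower (camera, adjusted p = 0.0105; adjusted p = 0.239 with an estimated correlation, and 0.428 with limma-voom), Postn (4.21) and the collagen gene Col1a1 (4.02) against Col1a2 (-2.64) and Pdgfrb (-2.20). Of 3 neuronal markers Tubb3 (1.96) and Eno2 (3.39) were higher and Map2 (-2.10) lower (adjusted p = 0.00373; adjusted p = 0.276 with an estimated correlation, 0.27 with limma-voom and 0.119 with no filter on low counts). Markers of epithelial carcinoma lines had 4 higher of 5 (adjusted p = 0.604), with Cdh1 at 2.24 ± 0.183 against 0.592 ± 0.126 CPM. The call of Krt17 among them (log2 fold change 0.98, adjusted p = 0.0163) was lost with DESeq2 (0.0613) and without STAT6 replicate 1 (0.0938) or 2 (0.0545) or Mock replicate 2 (0.0905) or 3 (0.0756). Blood cell markers had 2 higher of 3 (adjusted p = 0.755), with Cd68 at 2.13 ± 0.0744 against 0.571 ± 0.144 CPM. Nuclear-retained noncoding RNAs, which bear on RNA quality, had 6 higher and 3 lower of 13 (adjusted p = 0.737), with Neat1 at 0.60 and Tug1 at -0.34. Malat1, whose share is given beside that of the mtDNA genes, had a log2 fold change of 1.60 (adjusted p = 0.000679, edgeR). Replication-dependent histones, mostly without a poly(A) tail, had 3 higher and 3 lower of 12 (adjusted p = 0.755), with H1f2 at 1.93 and H2bc8 at -1.11. With fry all lists of this paragraph passed, at adjusted p from 3.72e-05 to 0.0312, as did nearly all lists tested. Counts adjusted over the list alone were the same.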

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

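The tests beyond 1.5-fold, with thinned libraries and without Gm26917 were chosen after the data were seen. Over the alternatives that kept all 6 libraries the number of changed genes ranged from 8727 (DESeq2) to 9942 (no filter on low counts), with 8716 to 9397 of them shared with the 9399 reported, and the number changed at least 2-fold from 1628 to 2772. Leaving out 1 library gave 9042 to 9476 changed genes, and 2106 to 2159 at least 2-fold. The one count that moved by more than 1.5 times was that of glmTreat, which asks for a change beyond 1.5-fold and called 2779 genes, 1807 higher and 972 lower. With library totals alone 42.5% of calls were higher, against 49.3% with TMM, and the median log2 fold change of all genes was -0.08. Stat6 stayed lower in all settings, with log2 fold changes from -1.56 to -1.46. The difference in mtDNA share stayed between 2.01 and 2.18 percentage points. The mtDNA list (median log2 fold change 0.32) lost its camera call with an estimated correlation (adjusted p = 0.672). That estimate was 0.64 against the preset 0.01, so the camera call rests on the preset value. Over the alternatives the adjusted p of the mtDNA list ran from 4.82e-05 to 0.672. The fusion and fission list (median 0.072) passed with fry (adjusted p = 0.0191), which asks whether the list's genes move on balance one way and not whether they differ from other genes; over its alternatives the adjusted p ran from 0.0191 to 0.876. Nuclear oxidative phosphorylation stayed above the threshold throughout, from 0.0757 to 0.993. Of the other values, 10 for named genes and 14 for lists fell short of the threshold, 11 of the latter with an estimated correlation. With that setting 4 of the 16 list calls of camera with the preset correlation were kept. For lists 38 values newly passed, most with fry, no filter or limma-voom. No call turned its direction, and in 16 cases a sign changed with neither setting past the threshold. The replicate block gave 9422 changed genes, 2018 at least 2-fold, and changed no named call. Libraries with the same number hardly deviated together (r of 0.031 to 0.102 over genes, against -0.083 to 0.035 for different numbers), and 5 of 6 correlated best with their own number, a hint from the data and not the design. The second principal component (3.36% of the variance) set replicate 2 of both groups apart. STAT6 replicate 2 lay at -14.93 and Mock replicate 2 at -15.55, the other libraries between 4.42 and 11.06. Depth limits genes near the floor of 3 counts, whose folds are bounds or have wide intervals.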

Other observations

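All tests of explanations here, the scan of neighbouring genes and the pigment and matrix lists were chosen after the results were seen. Pigment cell genes were abundant in both groups without a common direction. Of 18 tested, 10 were higher and 6 lower in the libraries labelled STAT6 (camera, adjusted p = 0.919, with a median log2 fold change of 0.14 and a test direction of down), and adjusted over the list alone the counts were the same. Gpnmb, a melanosome glycoprotein, rose (1.19) and so did Mc1r, the melanocortin receptor (0.85), whereas Tyr (-3.38) and Trpm1 (-1.55) fell. Extracellular matrix genes were mostly higher, 12 higher and 2 lower of 16, or 3 lower when adjusted over the list alone (adjusted p = 2.8e-09; adjusted p = 0.0232 with an estimated correlation). Sparc reached 2174 ± 22.1 CPM against 334 ± 7.52, and Col1a1 (4.02), Col6a1 (7.64) and Fn1 (1.90) rose with it.

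Neighbouring genes shifted together. In windows of 20 genes along the human gene order, 110 of 10233 window medians lay past the limits of 1000 shuffles, 53 above 0.84 and 57 below -0.54, and they joined into 11 blocks of 345 genes, 5 higher and 6 lower. The block from Plpp2 to Ap3d1 was the most pronounced: 48 of its 54 genes were called higher, with a median log2 fold change of 0.99, and it holds Ndufs7 (1.21), Uqcr11 (1.22) and Rps15 (1.34), named above, while Atp5d was not among the genes placed. Other blocks ran from Kifbp to Ddit4 (21 of 23 higher, median 0.85), Fyn to Rnf217 (25 of 31 higher, 0.76) and Lrrc61 to Ncapg2 (24 of 33 lower, -0.47), all chosen for their values. Of the other genes named above, Hk1 lies in the block from Kifbp to Ddit4 and Ogdh in that from Blvra to Abca13. Osmr, Hmgcs1 and Mrps30 lie in that from Wdr70 to Parp8, Insig1 and Fastk in that from Lrrc61 to Ncapg2. Ccnb1 lies in another lower block. Ccl2 and Ccl7 moved against the lower block that holds them. Hspb1 and Fis1 were higher in lower blocks too, but each is the first gene of its block, at the edge of a window.

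Chance placement would put any window past each limit in 5% of shuffles, and 110 windows of the observed order lay past them. Without 886 genes that had a family member near, 10 of the 10 blocks apart from the protocadherin one stayed past the limits, which argues against reads shared within families there; the block from Slc35a4 to Pcdhga3 did not, its median going from 0.68 to 0.06, so shared reads and a change of that family cannot be told apart. After trends on GC and length of the human transcripts, which stand in for mouse ones, were removed, 9 blocks stayed past the limits, which argues against these trends as their whole cause. They stay open for the 2 with no window left past the new limits of 0.81 and -0.53, such as Blvra to Abca13 (median 0.80, quartiles 0.32 and 1.10 before; 0.71, 0.38 and 1.13 after). A difference in copy number between the cells of both groups may underlie blocks, the largest median being 0.99, and cannot be told apart from regional regulation without DNA from these cells. Blocks that lie apart in the human order could be neighbours in the mouse, so 11 is no count of separate mouse regions, and whether STAT6 plays any part was not tested.

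The files and the labels differ in organism. Human 293T RNA counted on a mouse annotation would leave pigment cell genes near 0, yet the lowest sum of Tyrp1, Dct, Pmel, Mlana and Tyr in a library was 13920 CPM, while the neurofilament genes Nefl and Nefm, chosen after their values were seen, had at most 2 counts in a library. Files of another experiment than the labels describe remain a candidate explanation; that 6 of 6 libraries held at least 1000 CPM on these 5 genes is the observation that raised it and adds no support. The labels name 293T, and pigment cell transcripts of 13920 CPM or more in all 6 libraries argue against 293T RNA in these files. Beyond that, which cells were sequenced was not settled.

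Stat6 was lower in the libraries labelled STAT6 under every setting. Scaling of the libraries does not explain it: the value nearest 0 over all settings was a log2 fold change of -1.46. Exchanged group labels would lower the targets of STAT6 as a list only if STAT6 was active in these cells, which was not measured. Of 42 list members 13 were tested, and they went both ways, 4 higher and 6 lower with a median of -0.09. The list did not pass with camera (adjusted p = 0.815) and passed as higher with fry (0.00916, over a range of 0.00916 to 0.915 for its alternatives). As fry tests only against no change and most lists passed it, this pass does not bear on an exchange. With members on both sides and the activity of STAT6 not measured, an exchange cannot be told apart from labels that are right. A human STAT6 transgene not counted in these files stays open. Files of mouse symbols hold 0 rows for it whether or not it was present, so this count cannot decide. Such a transgene may be present beside a fall of the mouse gene. As to chance, the real split of the 6 libraries gave 9399 changed genes with edgeR. The highest of the 9 other splits gave 0 (52 at an unadjusted p under 0.05). Each other split had libraries of both groups on both sides, so the group difference widened the spread within them. Their low counts therefore say little about chance. With 1 of 10 splits reaching the real count, the splits are too few for a share under 0.05.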
